A study of Mus musculus with 15 samples.

How the data were processed

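The data are RNA sequencing libraries of total RNA from mouse pancreatic ductal organoids, hollow epithelial cultures grown in Matrigel. Per the labels' protocols, the medium held EGF, FGF10, gastrin, Noggin, R-spondin, nicotinamide, N-acetylcysteine and an inhibitor of TGF-β receptors, and was renewed 24 h before harvest in all cultures. Doxycycline at 1 µg/ml was added at different times so that all cultures were harvested together, per the labels' protocols. Ribosomal RNA was depleted and paired-end libraries were made with a TruSeq kit, per the labels' protocols; whether the counting used strand is not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart.

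Per the submitters' processing notes, the authors used kallisto 0.43.1 with GRCm38, and the notes also name DESeq2 1.18.1 and DESeq. The deposited files hold kallisto's estimated counts per transcript, not normalised, with transcript lengths and TPM values that sum to 1000000 per library, per the file headers and the values. Each file lists 109304 transcripts, 22 of them sequences added to the mouse transcriptome: EGFP, mKate2, rtTA3, resistance genes and 16 human transcripts. The deposited TPM values were used only as weights for a mean effective length per gene in 1 alternative.

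Estimated counts of mouse transcripts were summed per gene with the GENCODE M21 annotation of GRCm38, which may not be the release the authors used, and rounded to whole numbers. The 1295 transcript identifiers without a match held 0.56 to 0.59% of the counts of a library and were left out, which left 34554 genes and added sequences. The human transcripts were summed into 1 feature. Library totals ranged from 47915632 to 59411540, and mitochondrial and nuclear genes were kept together. For genes with 0 counts in a group, a fold was computed against a floor of 3 counts over the group, and ratios of few counts have 95% intervals; both cover counting error only, since reads carry no molecular identifiers.

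The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with TMM scaling, edgeR's default expression filter and a mean for each of the 6 groups, fitted to all 15 libraries so that they share an estimate of the spread. It tested 16462 features, 5 of them added sequences, which held 99.98% of the counts. TMM factors ranged from 0.966 to 1.023, and the biological coefficient of variation was 0.157, with 9 residual degrees of freedom. P-values were adjusted by Benjamini and Hochberg over all tested features within a comparison, and a feature was called below 0.05. The 9 comparisons were 4 h and 24 h against 0 h in each genotype, the difference of these responses between genotypes, and inducible against negative lines at each time. The comparisons, the tests, the alternatives, 30 gene lists from textbook knowledge and the rule for named genes were fixed before the data were examined. P-values measure the spread between these lines.

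Named genes were up to 10 per direction for a time comparison or difference of responses, with the largest log2 change among called genes with a mean of at least 1 CPM and the same sign in every line, leaving out predicted genes and pseudogenes. Up to 5 per direction were taken for a genotype comparison, missing ones were filled from the fit with the replicate block, and up to 4 members per list and glycan enzymes that passed in any comparison were added. Lists were tested with camera on log2 CPM with a preset correlation of 0.01 between genes (limma 3.58.1), adjusted over the 29 lists with at least 3 measured members. They were tested again with a correlation estimated from the data and with fry, both without the replicate block. Differences between lines therefore stay in both tests, and whether these account for lost calls was not tested. Camera with the replicate block kept the preset correlation. Medians of lists are from the main fit. Lists are described as higher or lower relative to all other genes.

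The same 5 lines were sampled at every time, so lines pair the libraries across times. Libraries of the same line deviated together from their group means, with a correlation of 0.381 to 0.476 over the 9 pairs of inducible lines. In negative lines it was 0.238 to 0.285, where deviations in a group of 2 mirror each other, so that both lines give the same values. Centring on group means makes correlations between different lines negative, so these are no evidence of pairing. The alternative fit with the line as a replicate block had a biological coefficient of variation of 0.058 and 6 residual degrees of freedom. Lines are nested in genotype, so genotype comparisons at 1 time could not take a fixed block; limma-voom with the line as a random block (correlation 0.417) covers them. Further alternatives were DESeq2 1.42.0, median-of-ratios scaling, no expression filter, a filter of 1 CPM in 3 libraries, an offset for effective length, leaving out the 1 gene with over 1% of counts, fitting only the compared groups, and leaving out each library and each line. Fits with a library or line left out held no replicate block. Thinning all libraries to 47648840 counts, correcting GC content and transcript length, and leaving out libraries in the list tests were added after the data were seen.

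The fitting code was tested on simulated counts for 16462 genes with 200 genes changed by 1.5-fold or 2-fold at 24 h in each genotype, 400 in all for the comparisons between genotypes. Changed genes were drawn from those with a mean of at least 1 CPM. For the main test the simulated libraries were independent and held no line effect. Its rates below therefore do not cover libraries paired by line, as the real ones are. For 24 h against 0 h in inducible lines it recovered 67% of the 1.5-fold and 88% of the 2-fold changes, with 6 false calls among 161, and in negative lines 42% and 78%. For the difference of 24 h responses the main test recovered 28% and 70.5%, and for inducible against negative lines at 24 h 60.5% and 85%. With the replicate block, 11 of 190 calls were false at 24 h in inducible lines, 15 of 189 in negative lines and 18 of 345 for the difference of 24 h responses. Where no gene was changed, that fit made 3 false calls at 4 h in inducible lines and 2 for the difference of 4 h responses, and the main test made 0. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 made the tables and figures.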

Results

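CA19-9 is a carbohydrate epitope, the sialylated Lewis a glycan. It is carried on secreted and membrane proteins and is measured in blood as a marker of pancreatic disease. Mice do not make it. The study used organoids from normal mouse pancreatic ducts in which doxycycline switches on the alleles needed for its synthesis. RNA was sequenced from 3 organoid lines carrying all required alleles (A217, A220 and A225, called inducible) and from 2 lines lacking a required allele (A218 and A223, called negative). Each line was sampled after 0, 4 and 24 h of doxycycline at 1 µg/ml, which gave 15 libraries, 1 for each line and time. The deposited estimated counts summed to between 47915632 and 59411540 per library. The 12 pairs of libraries from the same group differed by far more than sampling noise (chi-square per degree of freedom between 16.02 and 47.45). So no library of a group was a copy of another. The lines are counted as replicates, and the labels do not say how many animals they came from.

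The added EGFP sequence and the summed human transcripts, which stand for the induced alleles, were almost silent before doxycycline and high at 4 and 24 h in the inducible lines only. EGFP stood at 0.505 ± 0.207 counts per 1000000 with TMM scaling (CPM; SD, n = 3) at 0 h, 303 ± 40.6 at 4 h and 313 ± 63.1 at 24 h in inducible lines. In negative lines it stood at 0.236 ± 0.101 (n = 2), 0.221 ± 0.176 and 0.174 ± 0.025. The human transcripts, summed as human_transcripts, went from 2.13 ± 0.758 to 823 ± 115 and 853 ± 169 CPM in inducible lines. They stood at 0.89 ± 0.0606, 0.874 ± 0.227 and 1.41 ± 0.811 CPM in negative lines. Of the 16 human transcripts in the files, ENST00000398714.3 and ENST00000458379.6 held 99.9% of the counts. The files do not pair these identifiers with gene names. The log2 change of EGFP at 4 h was 9.24 ± 0.26 (SE; edgeR quasi-likelihood adjusted p = 7.07e-10) in inducible lines and -0.11 ± 0.71 (edgeR adjusted p = 1) in negative lines. The sequences of rtTA3, the doxycycline-dependent transcription activator, and mKate2, a red fluorescent protein, were present in all 15 libraries, at no less than 75.6 and 87.6 CPM. Mouse B3galt5 (chromosome 16, 96235801 to 96319859, GRCm38), a galactosyltransferase of the same pathway, stood at 0.378 ± 0.153 CPM at 0 h in inducible lines. Its changes of -0.63 at 4 h and -0.75 at 24 h did not pass (edgeR adjusted p = 0.886 and 0.428).

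**Figure D1:**
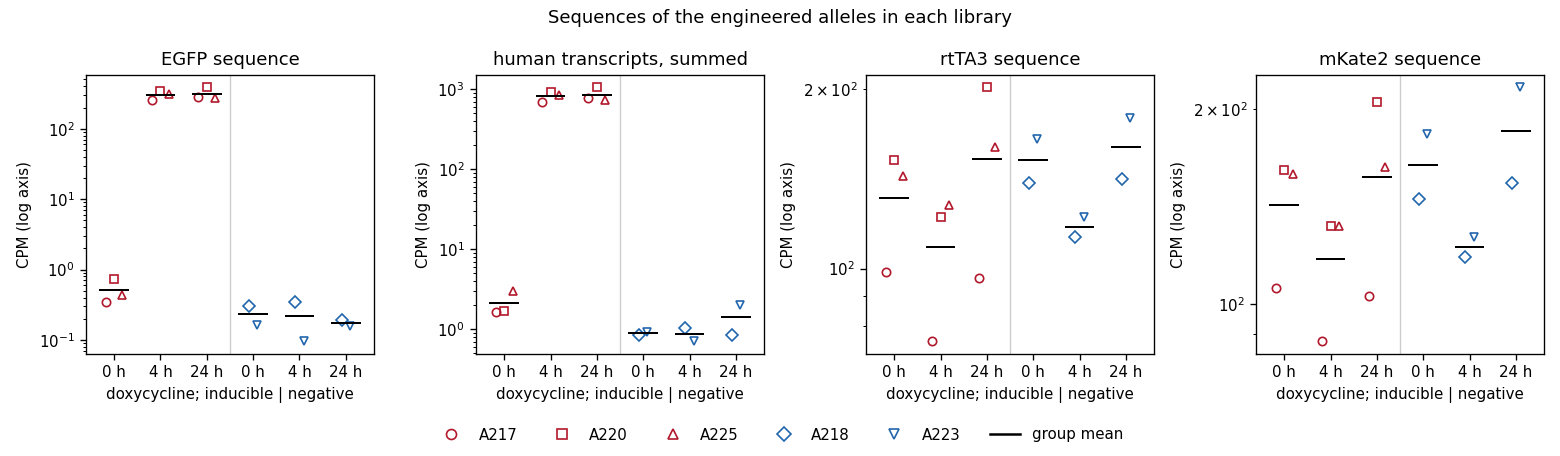
CPM on log axes of EGFP, the summed human transcripts, rtTA3 and mKate2 in each of the 15 libraries, by hours of doxycycline, with inducible lines in red on the left and negative lines in blue on the right, a symbol per line and a bar at each group mean. EGFP lies at 303 and 313 CPM on average at 4 and 24 h in inducible lines and under 1 CPM in every negative library, while rtTA3 and mKate2 lie at 75.6 CPM or more in all libraries.

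After 4 h of doxycycline the main test, which does not pair libraries of a line, called few features in inducible lines beyond the alleles themselves. It called 49, against 502 with the line as a replicate block and 273 with limma-voom and a random block. Oprd1, the delta opioid receptor (ENSMUSG00000050511.1, chromosome 4, 132110726 to 132144486), rose from 4.02 ± 0.843 to 39.3 ± 7.83 CPM (n = 3), 9.78-fold. Clock, the core circadian transcription factor (ENSMUSG00000029238.11, chromosome 5, 76209868 to 76304792), rose from 97.1 ± 4.96 to 232 ± 27.9 CPM. Csf1, the macrophage colony-stimulating factor, rose from 4.07 ± 0.521 to 10.2 ± 1.19 CPM. Gclc, the catalytic subunit of the rate-limiting enzyme of glutathione synthesis (ENSMUSG00000032350.9, chromosome 9, 77754535 to 77794485), fell from 704 ± 57.4 to 372 ± 25.7 CPM.

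The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 49 of 16462 features at 4 h against 0 h in inducible lines, 37 higher and 12 lower. Of these 17 moved by more than 2-fold. The rises and falls below are ranked by the naming rule, only among genes with a mean of at least 1 CPM. Besides Oprd1 (log2 change 3.29 ± 0.19, edgeR adjusted p = 1.5e-06), Csf1 (1.32 ± 0.17, 0.00313) and Clock (1.26 ± 0.13, 0.000972), the rises of the largest size were those of Slc29a3, a nucleoside transporter (1.25), Chic2 (1.23), Tmem165, a Golgi ion transporter needed for glycosylation (1.22), Eea1, an early endosome tether (2.26-fold), Cpeb2, an RNA-binding translation regulator (1.12), Fkbpl (1.04) and Nrip3 (0.99). The falls of the largest size were those of Gclc (-0.92 ± 0.1, edgeR adjusted p = 0.000972), Osgin1, an oxidative stress response gene (-0.66), Slc7a11, the cystine importer (-0.57), Srxn1, sulfiredoxin (-0.54), Tsku, a secreted signalling modulator (-0.53), Myc, the growth-promoting transcription factor (-0.44), Ppan, a ribosome biogenesis factor (-0.34), Srsf5, a splicing factor (-0.3), Ssbp3 (-0.25) and Urb2, another ribosome biogenesis factor (-0.23). Some genes with few counts rose more. Muc13, a transmembrane mucin, rose 16.7-fold (8.23 to 39.5, 95% counting interval) from 8 counts over the 3 libraries. Vstm2b went from 2 to 148 counts, a ratio of 74.8 (20.4 to 624). Nmu, the neuropeptide neuromedin U, had 0 counts at 0 h and 69 at 4 h, at least 23.3-fold higher against a floor of 3 counts over the group. It was named after its values were seen. With the organoid line as a replicate block the test called 502 genes, 219 higher and 283 lower. Without 1 library the count was 33 (0 h A217), 20 (0 h A220), 30 (0 h A225), 35 (4 h A217), 28 (4 h A220) or 26 (4 h A225). Of the 25 named genes called, between 8 (without 0 h A217) and 13 (without 0 h A220) lost the call. There were 8 lost without 0 h A225 or 4 h A217, 10 without 4 h A220 and 11 without 4 h A225.

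Among the gene lists fixed beforehand, the targets of the antioxidant regulator NRF2 together with metal-response genes were lower at 4 h, and the unfolded protein genes of the endoplasmic reticulum were higher. Of 21 measured NRF2 and metal genes, 4 fell (Gclc, Srxn1, Slc7a11, Osgin1), 7 fell when adjusted over the list alone and 10 with the replicate block. These genes had a median log2 change of -0.2. The list passed camera (adjusted p = 8.33e-12; adjusted p = 0.0101 with an estimated correlation). Of 19 unfolded protein genes none passed edgeR's test over all genes. Hspa5, the main chaperone of the endoplasmic reticulum, had a log2 change of 0.21 (edgeR adjusted p = 0.241) and Dnajb9, a co-chaperone, of 0.46 (edgeR adjusted p = 0.197). In this list 5 rose when adjusted over the list alone and 4 with the replicate block. That list passed camera too (adjusted p = 3.33e-07; adjusted p = 0.0201 with an estimated correlation). The remaining 4 lists past camera's threshold lost the call with an estimated correlation. The genes encoded in mitochondrial DNA were higher (camera adjusted p = 0.00264; adjusted p = 0.546 with an estimated correlation; 0 of 13 called, 0 when adjusted over the list alone). That call ended without 0 h A220 (camera adjusted p = 0.103). Inflammation genes were higher (camera adjusted p = 0.00107; adjusted p = 0.546 with an estimated correlation), with only Csf1 of 31 called and 2 when adjusted over the list alone. This ended without 0 h A225 (0.147) or 4 h A220 (0.0706). Proliferation genes were lower (camera adjusted p = 0.000299; adjusted p = 0.704 with an estimated correlation) with 0 of 35 called on either adjustment. This ended without 0 h A217 (0.0593) or 4 h A220 (0.305). Hypoxia and glycolysis genes were lower (camera adjusted p = 0.0143; adjusted p = 0.769 with an estimated correlation) with 0 of 27 called on either adjustment. The list has 26 symbols, of which Aldoa has 2 gene identifiers. That call ended without 4 h A217 (0.77) or 4 h A220 (0.0706) and turned to higher without 0 h A220 (0.935). With the replicate block 3 more lists passed as lower, ERK targets (camera adjusted p = 0.0212), WNT targets (0.0172) and Notch and YAP targets (0.0461). Without the block, camera with an estimated correlation gave adjusted p = 0.546 for each. Each also passed without the block when certain single libraries were left out, ERK targets without 0 h A217 (0.000989) or 4 h A225 (0.0199), WNT targets without 0 h A225 (0.00229) or 4 h A217 (0.0147), and Notch and YAP targets without 0 h A217 (0.0185).

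At 24 h the inducible lines had changed many more genes, mostly by small amounts. Oprd1 reached 72.6 ± 14.1 CPM (n = 3), 18.1-fold above 0 h. Gstm5, a glutathione S-transferase, rose from 17.9 ± 1.6 to 99.8 ± 13.9 CPM, 5.57-fold. Angptl4, an inhibitor of lipoprotein lipase, rose from 6.58 ± 2.98 to 31.2 ± 12.3 CPM. Sgk1, a kinase induced by serum and glucocorticoids, rose from 12.9 ± 4.12 to 32.2 ± 9.26 CPM. Ankrd37, a target of the hypoxia-inducible factors, fell from 9.4 ± 4.31 to 2.71 ± 0.743 CPM. Banp, a transcription factor that binds unmethylated CpG motifs, fell from 19.9 ± 1.98 to 11.3 ± 2.13 CPM.

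**Figure D2:**
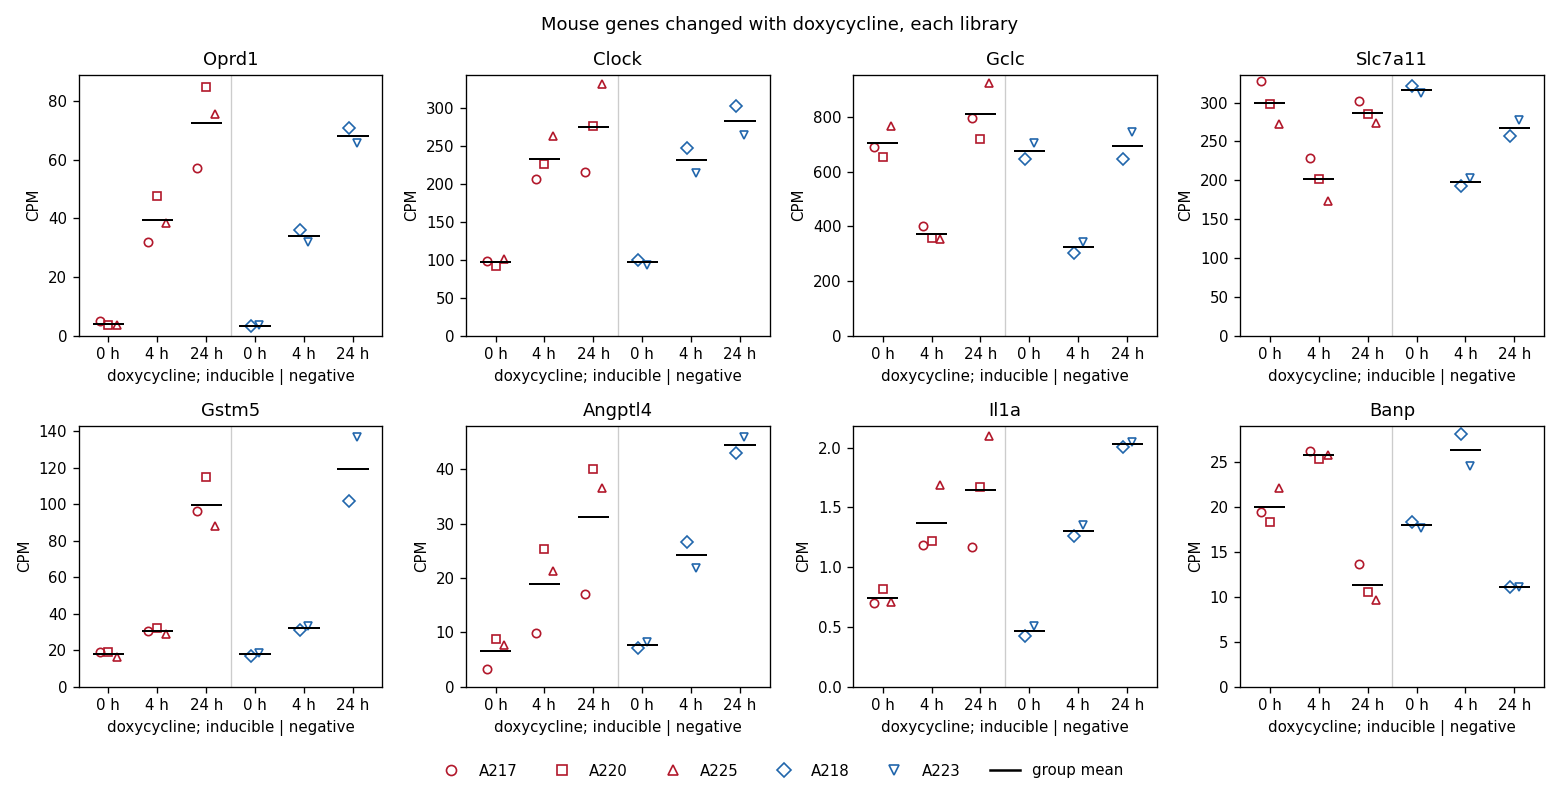
CPM on linear axes from 0 of 8 mouse genes in each of the 15 libraries, by hours of doxycycline, with inducible lines in red on the left and negative lines in blue on the right, a symbol per line and a bar at each group mean. Oprd1 lies at 4.02 CPM on average at 0 h and 72.6 at 24 h in inducible lines, and at 3.46 and 68.2 in negative lines, while Gclc is lowest at 4 h in both.

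The edgeR test called 812 features at 24 h against 0 h in inducible lines, 567 higher and 245 lower. Of these 77 moved by more than 2-fold. Fitted to the compared groups alone the test called 65, 64 higher and 1 lower, while DESeq2 called 1804. With GC content and transcript length corrected, an alternative chosen after the data were seen, the split was 689 higher and 540 lower. The largest rises among named genes, with their log2 changes, were those of Oprd1 (4.18 ± 0.19, edgeR adjusted p = 1.16e-07), Bcl2l15, a member of the BCL2 family (2.62), Pcp4l1 (2.56), Gstm5 (2.48 ± 0.13, edgeR adjusted p = 2.52e-07), Gng2, a G protein subunit (2.29), Angptl4 (2.25 ± 0.41, edgeR adjusted p = 0.00979), Nebl, the actin-binding protein nebulette (2.24), Mylk, myosin light chain kinase (2.24), and Ephx2, soluble epoxide hydrolase (2.02). Vstm2b (ENSMUSG00000039257.11, chromosome 7, 40898328 to 40930594) went from 2 to 1252 counts over 3 libraries, a ratio of 708 (195 to 5850, 95% counting interval). Muc13 rose 30.8-fold (15.4 to 72.3). Nmu went from 0 to 207 counts, at least 78-fold higher against the floor of 3 counts. The largest falls were those of Ankrd37 (-1.8 ± 0.35, edgeR adjusted p = 0.0145), Mtfp1, a mitochondrial fission protein (-1.05), Hexim2, an inhibitor of transcription elongation (-0.95), Adamts1, a secreted metalloprotease (-0.93), Fut1, the fucosyltransferase that makes the H antigen (-0.88), Slc6a20b, an amino acid transporter (-0.86), Hist2h3c1, a histone H3 gene (-0.85), Trim6, a ubiquitin ligase (-0.82), Banp (-0.82 ± 0.12, edgeR adjusted p = 0.0025) and Klhl23 (-0.81). The fit with the replicate block called 3987 genes, 2305 higher and 1682 lower. Without 1 library the count was 227 (0 h A217), 426 (0 h A220), 370 (0 h A225), 2002 (24 h A217), 220 (24 h A220) or 245 (24 h A225). Of the 65 named genes called, 37, 29, 27, 2, 36 and 37 lost the call in that order, and 24 kept it in all of these fits.

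By gene list, inflammation genes, duct markers and genes encoded in mitochondrial DNA were higher at 24 h in inducible lines. Lower were proliferation, mitochondrial ribosome, and hypoxia and glycolysis genes. All 10 lists past camera's threshold lost the call with an estimated correlation. That estimate was made without the replicate block, so differences between lines stay in it. Of 31 inflammation genes 6 rose and 1 fell, and 12 rose and 1 fell when adjusted over the list alone (camera adjusted p = 2.78e-05; adjusted p = 0.315 with an estimated correlation). They were the growth factors Csf1 (log2 change 1.63) and Csf2 (1.52), the cytokines Il1a (1.15) and Il18 (0.88), the adhesion molecule Icam1 (0.38), the chemokine Cxcl16 (0.35) and, lower, the NF-κB modulator Nfkbiz (-0.53). Of 17 duct markers 3 rose, Tspan8 (0.58), Krt8 (0.45) and Krt18 (0.42), and 4 when adjusted over the list alone (camera adjusted p = 0.00729; adjusted p = 0.315 with an estimated correlation). Of 13 genes of mitochondrial DNA 4 rose, mt-Nd2 (0.8), mt-Nd4 (0.7), mt-Cytb (0.64) and mt-Nd4l (0.62), all subunits of respiratory complexes, and 7 when adjusted over the list alone (camera adjusted p = 0.0001; adjusted p = 0.482 with an estimated correlation). The share of all counts from these genes was 0.87% ± 0.06 at 0 h, 0.96% ± 0.06 at 4 h and 0.99% ± 0.09 at 24 h (SD, n = 3). Glucocorticoid targets were higher, with Sgk1 (1.32) called and 2 of 10 when adjusted over the list alone (camera adjusted p = 0.0154; adjusted p = 0.315 with an estimated correlation). Of 35 proliferation genes 2 fell, the mitotic kinase Aurkb (-0.38) and the replication licensing factor Cdc6 (-0.48), and 12 when adjusted over the list alone (camera adjusted p = 2.15e-09; adjusted p = 0.482 with an estimated correlation). Of 27 hypoxia and glycolysis genes 5 fell, Ankrd37, the prolyl hydroxylases Egln1 (-0.41) and Egln3 (-0.65) and the glycolytic enzymes Pfkp (-0.57) and Hk2 (-0.53), and 6 when adjusted over the list alone (camera adjusted p = 0.000165; adjusted p = 0.673 with an estimated correlation).

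Of 27 mitochondrial ribosome genes 1 fell, Mrps18b (-0.26), and 4 when adjusted over the list alone (camera adjusted p = 4.66e-05; adjusted p = 0.482 with an estimated correlation). The mitochondrial unfolded protein list was lower, with the chaperone Dnaja3 (-0.15) called of 12 and 3 when adjusted over the list alone (camera adjusted p = 0.0445; adjusted p = 0.482 with an estimated correlation). The integrated stress list was lower too, with the serine pathway enzyme Shmt2 (-0.36) and the stress cytokine Gdf15 (-0.69) called of 36 and 3 when adjusted over the list alone (camera adjusted p = 0.0445; adjusted p = 0.673 with an estimated correlation). Cholesterol synthesis genes were higher, with the sterol sensor Insig1 (0.71) and the enzyme Nsdhl (0.36) called of 24 on either adjustment, 2 when adjusted over the list alone (camera adjusted p = 0.0487; adjusted p = 0.828 with an estimated correlation; 0.0777 with the replicate block). The mitochondrial unfolded protein call ended without 0 h A217 (camera adjusted p = 0.107), 24 h A220 (0.099) or 24 h A225 (0.0509). The integrated stress call ended without 0 h A220 (0.329), 24 h A217 (0.112) or 24 h A220 (0.0786). The cholesterol call ended without 0 h A217 (0.0783), 0 h A225 (0.517), 24 h A217 (0.154) or 24 h A220 (0.115). Notch and YAP targets did not pass (camera adjusted p = 0.065, and 0.482 with an estimated correlation). They passed as higher with the replicate block (camera adjusted p = 0.0361) and without 0 h A225 (0.0211). The growth factor regulator Crim1 (0.24) was called in the fit without the block.

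The negative lines, which could not switch on CA19-9 synthesis, also changed with doxycycline. At 4 h Oprd1 rose from 3.46 ± 0.047 to 34 ± 2.79 CPM (n = 2), 9.82-fold. Clock rose from 97 ± 4.55 to 232 ± 23.6 CPM. Gclc fell from 676 ± 39.1 to 323 ± 28.1 CPM and Slc7a11 from 317 ± 6.32 to 198 ± 7.08 CPM. The edgeR test called 20 genes at 4 h against 0 h, 16 higher and 4 lower, of which 9 moved by more than 2-fold. The rises below are ranked by the naming rule, only among genes with a mean of at least 1 CPM. The rises of the largest size were those of Oprd1 (log2 change 3.3 ± 0.23, edgeR adjusted p = 5.67e-05), Clock (1.25 ± 0.16, edgeR adjusted p = 0.00815), Slc29a3 (1.24), Fkbpl (1.16), Cdkn2d, a cyclin-dependent kinase inhibitor (1.12), Chic2 (1.09), Nrip3 (0.96), Cttnbp2nl (0.92), Chml, a Rab escort protein (0.89), and Adgrg1, an adhesion G protein-coupled receptor (0.81). The 4 falls were those of Gclc (-1.07 ± 0.12, edgeR adjusted p = 0.0038), Slc7a11 (-0.68), Myc (-0.57) and Sh3pxd2b, a podosome adaptor (-0.36). Nmu went from 0 to 59 counts, at least 20.7-fold higher. With the replicate block the test called 336 genes, 132 higher and 204 lower. That fit, unlike the fit without the block, called Pou2f2, a B-cell transcription factor (-1.68), and Zbtb20, a transcriptional repressor (-0.84; edgeR adjusted p with the block = 0.049 and 0.0181). Without 1 library the count was 3 (0 h A218), 2 (0 h A223), 5 (4 h A218) or 9 (4 h A223). Of the 15 named genes called, 12, 13, 12 and 8 lost the call. Oprd1 and Nrip3 kept it in all 4 fits.

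The NRF2 and metal list was lower in negative lines at 4 h as well, with Gclc and Slc7a11 called of 21, 7 when adjusted over the list alone and 8 with the replicate block (camera adjusted p = 3.29e-12; adjusted p = 0.00894 with an estimated correlation). All other 9 lists past camera's threshold lost the call with an estimated correlation. ERK targets were lower, with Myc called of 25 and 1 when adjusted over the list alone (camera adjusted p = 0.0018; adjusted p = 0.465 with an estimated correlation). Genes of mitochondrial DNA were higher, 0 of 13 called and 1 when adjusted over the list alone (camera adjusted p = 4.12e-05; adjusted p = 0.465 with an estimated correlation; 0.118 without 4 h A223). The share of all counts from these genes was 0.76% ± 0.03 at 0 h and 0.96% ± 0.05 at 4 h (SD, n = 2). Inflammation genes were higher with 0 of 31 called and 2 when adjusted over the list alone (camera adjusted p = 0.0159; adjusted p = 0.533 with an estimated correlation; 0.0879 without 0 h A223, 0.492 without 4 h A218). Duct markers were lower with 0 of 17 called and 2 when adjusted over the list alone (camera adjusted p = 0.0104; adjusted p = 0.38 with an estimated correlation; 0.252 without 4 h A223). Hypoxia and glycolysis genes were higher with 0 of 27 called on either adjustment (camera adjusted p = 0.019; adjusted p = 0.94 with an estimated correlation; 0.373 without 0 h A218, 0.607 without 4 h A223). The unfolded protein list was higher with 0 of 19 called and 1 when adjusted over the list alone (camera adjusted p = 0.0423; adjusted p = 0.465 with an estimated correlation; 0.0579 with the replicate block; 0.415 without 0 h A223, 0.381 without 4 h A218, 0.0824 without 4 h A223). Integrated stress genes were lower with Slc7a11 called of 36 and 2 when adjusted over the list alone (camera adjusted p = 0.0317; adjusted p = 0.793 with an estimated correlation; 0.869 without 0 h A223, 0.484 without 4 h A218). WNT targets (camera adjusted p = 0.0297; adjusted p = 0.596 with an estimated correlation; 0.16 without 0 h A218, 0.0844 without 4 h A218, 0.153 without 4 h A223) and Notch and YAP targets (camera adjusted p = 0.0317; adjusted p = 0.465 with an estimated correlation; 0.305 without 0 h A218, 0.532 without 4 h A223) were lower with 0 of 14 members called in each, on either adjustment.

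After 24 h the negative lines had raised Oprd1 to 68.2 ± 3.59 CPM (n = 2), 19.7-fold. Gstm5 rose from 17.7 ± 1.42 to 119 ± 25.2 CPM and Angptl4 from 7.65 ± 0.85 to 44.5 ± 1.98 CPM. Il1a, an alarmin cytokine, rose from 0.468 ± 0.0626 to 2.03 ± 0.0269 CPM. Banp fell from 17.9 ± 0.491 to 11.1 ± 0.0305 CPM. The edgeR test called 625 genes, 450 higher and 175 lower, of which 79 moved by more than 2-fold. Fitted to the compared groups alone it called 1734, 987 higher and 747 lower. With GC content and transcript length corrected, an alternative chosen after the data were seen, the split was 533 higher and 339 lower. The rises and falls below are ranked by the naming rule, only among genes with a mean of at least 1 CPM. The largest rises were those of Oprd1 (log2 change 4.3 ± 0.24, edgeR adjusted p = 1.85e-06), Muc13 (11.5-fold, 7.17 to 19.4), Pcp4l1 (2.88), Gng2 (2.88), Gstm5 (2.76 ± 0.15, edgeR adjusted p = 1.85e-06), Angptl4 (2.54), Mylk (2.47), Ephx2 (2.24) and Il1a (2.11 ± 0.3, edgeR adjusted p = 0.00291). Vstm2b went from 0 to 892 counts over 2 libraries, at least 306-fold higher. Nmu went from 0 to 151 counts, at least 51.8-fold higher. The largest falls were those of Pou2f2 (-1.77), Adamts1 (-1.29), Frat2, a WNT pathway activator (-1), Foxc1, a forkhead transcription factor (-0.88), Spats2l (-0.79), Lrrc75a (-0.78), Ticrr and Cdc7, which act in replication origin firing (-0.77 and -0.75), Hpse, heparanase (-0.7), and Banp (-0.7). The fit with the replicate block called 3696 genes, 2242 higher and 1454 lower. Without 1 library the count was 54 (0 h A218), 56 (0 h A223), 129 (24 h A218) or 73 (24 h A223). Of the 48 named genes called, 39, 39, 31 and 38 lost the call.

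In the negative lines at 24 h, inflammation genes, duct markers and genes of mitochondrial DNA were again higher and proliferation genes lower. All 7 lists past camera's threshold lost the call with an estimated correlation, which was again estimated without the replicate block. Of 31 inflammation genes 8 rose, among them Icam1 (log2 change 0.72), Csf1 (1.84), Il1a (2.11), Cxcl16 (0.54), Il18, Csf2 (1.53), the NF-κB subunit Relb (0.84) and the NF-κB inhibitor Tnfaip3 (0.59). In this list 12 rose and 1 fell when adjusted over the list alone (camera adjusted p = 1.63e-05; adjusted p = 0.349 with an estimated correlation). Of 17 duct markers 4 rose, Tspan8 (0.81), Krt8 (0.66), Krt18 (0.62) and the tight junction protein Cldn4 (0.78), and 4 when adjusted over the list alone (camera adjusted p = 0.0152; adjusted p = 0.349 with an estimated correlation; 0.057 without 24 h A223). Of 35 proliferation genes Rrm2, a ribonucleotide reductase subunit (-0.47), and Mcm6, a helicase subunit (-0.34), fell, and 21 when adjusted over the list alone (camera adjusted p = 2e-11; adjusted p = 0.802 with an estimated correlation). Of 13 genes of mitochondrial DNA mt-Cytb (0.86) rose, and 8 when adjusted over the list alone (camera adjusted p = 0.00195; adjusted p = 0.802 with an estimated correlation; 0.0946 without 24 h A223). Their share of all counts was 0.89% ± 0.13 (SD, n = 2). Mitochondrial ribosome genes were lower with 0 of 27 called on either adjustment and 9 with the replicate block (camera adjusted p = 0.000797; adjusted p = 0.802 with an estimated correlation). Glucocorticoid targets were higher with Sgk1 (1.36) called of 10 and 1 when adjusted over the list alone (camera adjusted p = 0.0165; adjusted p = 0.349 with an estimated correlation; 0.0946 without 24 h A223). Cholesterol genes were higher with Insig1 (0.71) called of 24 and 1 when adjusted over the list alone (camera adjusted p = 0.0128; adjusted p = 0.835 with an estimated correlation; 0.197 without 0 h A218, 0.0946 without 24 h A223). Notch and YAP targets did not pass (camera adjusted p = 0.1, and 0.802 with an estimated correlation). They passed as higher with the replicate block (camera adjusted p = 0.0367).

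Most genes that changed in the inducible lines moved the same way in the negative lines. Of the 810 mouse genes called at 24 h in inducible lines, 801 (98.9%) had the same sign in negative lines. The genes called higher had median log2 changes of 0.37 and 0.4 in the 2 genotypes. Those called lower had -0.37 and -0.34. There were 323 genes called higher in both genotypes, where independent lists of these sizes would share 15.45. There were 66 called lower in both, against 2.61. At 4 h, 46 of 47 called mouse genes had the same sign. Of them 15 were called higher in both, against 0.03, and 3 called lower, against 0. Across the 12215 mouse genes of at least 1 CPM the log2 changes of the genotypes had a Pearson r of 0.317 at 4 h and 0.586 at 24 h. Over all 16457 tested mouse genes, which include those with few counts, r was -0.014 at 4 h and 0.292 at 24 h. Genes are not independent replicates. The 2 genotypes share no libraries, so these overlaps hold no shared controls. Both lists come from a fit with a shared spread per gene, so genes of low spread are more readily called in both. The overlaps given for independent lists leave this out.

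**Figure D3:**
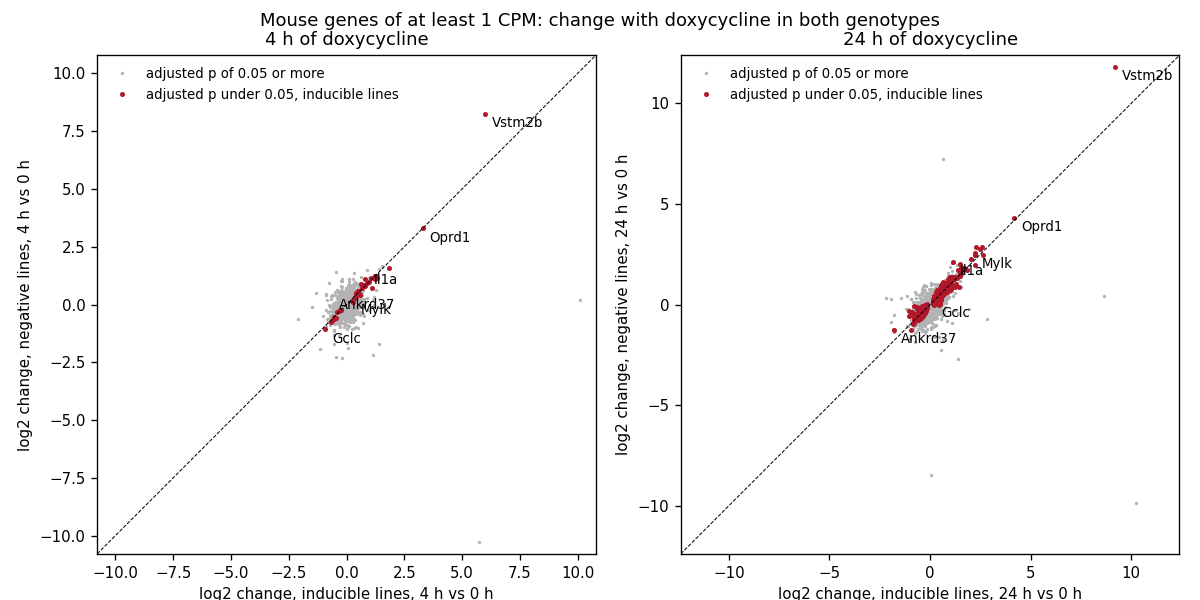
Log2 change with doxycycline in negative lines (vertical axis) against that in inducible lines (horizontal axis) at 4 h (left) and 24 h (right), with a point for each mouse gene of at least 1 CPM and red points for genes with an adjusted p under 0.05 in inducible lines. At 24 h, 781 of the 784 red genes have the same sign on both axes, and the fitted position of Vstm2b, which had 0 counts in negative lines at 0 h, is not a bound on its change.

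The test of the difference between genotypes asks which genes responded in inducible lines beyond the response of negative lines, which also hold rtTA3. In the main edgeR fit it passed only for EGFP and the human transcripts. The difference of the 4 h responses, inducible minus negative, was 9.34 ± 0.99 log2 units for EGFP (edgeR adjusted p = 0.00348) and 8.61 ± 0.62 for human_transcripts (edgeR adjusted p = 8.24e-05). At 24 h it was 9.71 ± 1.01 (edgeR adjusted p = 0.0028) and 7.97 ± 0.6 (edgeR adjusted p = 0.000135). No mouse gene passed in that fit, while 236 features at 4 h and 414 at 24 h had an unadjusted p under 0.05. Oprd1 stood at 72.6 ± 14.1 and 68.2 ± 3.59 CPM in inducible and negative lines at 24 h, and Gclc at 372 ± 25.7 and 323 ± 28.1 CPM at 4 h. For mouse genes of at least 1 CPM the 95% interval of the difference lay within 2-fold for 87.4% at 4 h and 87.2% at 24 h. It lay within 1.5-fold for 71.2% and 70.1%. In the median gene it reached 0.32 log2 units to either side, while genes called higher at 24 h in inducible lines rose by a median of 0.37. On simulated counts this test recovered 28% of 1.5-fold differences at 24 h. Differences as large as many of the responses are therefore not excluded. Without negative 0 h A218 the EGFP differences no longer passed (edgeR adjusted p = 0.781 at 4 h and 0.639 at 24 h), leaving human_transcripts as the 1 feature called. In the fit with the replicate block 3 features passed at 4 h and 4 at 24 h. The added ones were the pseudogenes Gm10221, Gm9845 and Gm5537, named after their values were seen. Gm9845 also passed at 24 h in edgeR with no expression filter (8.97, edgeR adjusted p = 0.0126). On simulated counts with no change at 4 h the fit with the block called 2 features for this difference, against the 1 added at 4 h here. DESeq2 called 5 at each time, of which 3 were mouse pseudogenes, Gm9845 and Gm5537 at both times with Gm2436 at 4 h and Pgam1-ps2 at 24 h.

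Of the gene lists, hypoxia and glycolysis genes differed between genotypes in their 4 h response, with a median difference of -0.22 log2 units over 27 genes (camera adjusted p = 7.67e-07; adjusted p = 1 with an estimated correlation). No member passed on either adjustment, 0 when adjusted over the list alone. The glycolytic enzymes Tpi1 and Ldha had differences of -0.31 and -0.24 (edgeR adjusted p = 1 for both). The call ended without negative 4 h A223 (camera adjusted p = 0.0863). At 24 h no list passed camera. In the fit with the replicate block inflammation (camera adjusted p = 0.00151), proliferation (0.0357) and hypoxia and glycolysis (0.0364) passed. Their median differences without the block were -0.16, 0.07 and -0.13. Without the block, camera with an estimated correlation gave adjusted p = 0.974 for each. The unfolded protein list passed with the block at 4 h (camera adjusted p = 0.0372). Without the block its median was 0.06, with camera adjusted p = 1 with an estimated correlation. The enzymes and transporters that build Lewis glycans did not pass in any comparison, with camera adjusted p values for the difference of 0.817 at 4 h and 0.903 at 24 h. Of 29 measured members only Fut1 was called, at 24 h in inducible lines, with 0 when adjusted over the list alone. Fut1 lost the call without any 1 of the 6 libraries in fits with no replicate block (edgeR adjusted p between 0.0581 and 0.177, the highest without 24 h A225). The EGF receptor and its ligands did not pass either (camera adjusted p = 0.554 at 4 h and 0.917 at 24 h for the difference). Of 15 measured members 1, the ligand Hbegf, rose at 24 h in negative lines (log2 change 0.57, edgeR adjusted p = 0.0409), where 1 rose when adjusted over the list alone. Hbegf lost that call without any 1 of the 4 libraries, in fits with no replicate block that leave 1 library in a group. It had 0.41 in inducible lines (edgeR adjusted p = 0.0575).

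Direct comparison of inducible with negative lines found no mouse gene at any time in the main edgeR fit, while DESeq2 called 5, 9 and 12 mouse genes at 0, 4 and 24 h. Before doxycycline EGFP and human_transcripts were 1.08 ± 0.54 and 1.27 ± 0.39 log2 units higher in inducible lines, which did not pass (edgeR adjusted p = 1 for both). At 4 h they were 10.43 ± 0.35 (edgeR adjusted p = 5.82e-09) and 9.88 ± 0.39 (edgeR adjusted p = 2.68e-08) higher, and at 24 h 10.79 ± 0.36 (edgeR adjusted p = 5.05e-09) and 9.24 ± 0.38 (edgeR adjusted p = 3.53e-08). The count of features called by edgeR was 0 at 0 h, where 589 had an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 5. Those 5, named after their values were seen, were Tm4sf4, a tetraspanin-like membrane protein (log2 difference 0.42), Plxnd1, a semaphorin receptor (-1.38), Syce1, a meiotic protein (-8.04, at a mean of 0.732 CPM), Gm9845 and Gm2436. DESeq2 called Plxnd1 and Syce1 at 4 h (-1.25 and -8.98) and 24 h (-1.16 and -7.14) too. Syce1 also passed edgeR with no expression filter at 4 h (-9.5, edgeR adjusted p = 0.0155) and 24 h (-6.91, edgeR adjusted p = 0.0355). At 4 and 24 h edgeR called 2 features each and DESeq2 11 and 14. Integrated stress genes were lower in inducible lines at 0 h (camera adjusted p = 0.000493; adjusted p = 0.982 with an estimated correlation; 0.555 without negative A223) and at 24 h (camera adjusted p = 1.35e-05; adjusted p = 0.87 with an estimated correlation; 0.137 without negative A223), with 0 of 36 called at either time and 0 and 1 when adjusted over the list alone. At 4 h the unfolded protein genes were higher (camera adjusted p = 0.000136; adjusted p = 0.165 with an estimated correlation), with 0 of 19 called and 1 when adjusted over the list alone. Hypoxia and glycolysis genes were lower at 4 h (camera adjusted p = 6.25e-09; adjusted p = 0.687 with an estimated correlation) and at 24 h (camera adjusted p = 0.0399; adjusted p = 0.975 with an estimated correlation; 0.307 without A217, 0.0723 without A225, 0.467 without A223), with 0 of 27 called on either adjustment. The p53 targets were higher at 4 h (camera adjusted p = 0.0413; adjusted p = 0.855 with an estimated correlation; 0.363 without A220, 0.114 without A225, 0.468 without A218), with 0 of 20 called on either adjustment.

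The cultures were made of duct cells by their markers, and most markers of other pancreatic cell types were low, as means over all 15 libraries. Duct markers had a median of 431 CPM over 17 genes, led by the keratin Krt8 at 4510 CPM. The highest acinar marker, Cela1, stood at 1.27 CPM, the highest endocrine marker, Pcsk2, at 0.553, and the highest mesenchymal marker, Tagln, at 1.98. Of the immune markers Cd14 stood at 83.7 CPM and of the endothelial markers Egfl7 at 17.5 CPM, both of which epithelial cells can express. Over 1 CPM stood 3 of 16 immune, 3 of 12 endothelial, 2 of 16 mesenchymal, 1 of 29 acinar and 0 of 17 endocrine markers. The acinar gene Sycn rose at 24 h in both genotypes, from 0.189 ± 0.0768 to 1.17 ± 0.57 CPM (n = 3; log2 change 2.63, edgeR adjusted p = 0.00581) in inducible lines and from 0.227 ± 0.114 to 1.43 ± 0.0903 CPM (n = 2; 2.64, edgeR adjusted p = 0.0155) in negative lines. In negative lines the call was lost without any 1 of the 4 libraries, in fits with no replicate block that leave 1 library in a group.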

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

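The tests of the alleles as the whole cause, of depth, of GC content and length, of doxycycline against rtTA3, of chance placement and of a rise of the whole region were chosen only after the results were seen. The tests of shared sequence and the splits of the libraries were set before their values were seen.

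EGFP and the human transcripts, the sequences of the induced alleles, responded differently in the 2 genotypes. The difference of the 4 h responses was 9.34 log2 units for EGFP and 8.61 for human_transcripts, and at 24 h it was 9.71 and 7.97. Without negative 0 h A218, the EGFP differences no longer passed (edgeR adjusted p = 0.781 at 4 h and 0.639 at 24 h). They were also lost without all libraries of line A218 (0.552 and 0.688), A223 (0.0764 and 0.0521) or A225 (0.0721 and 0.0568).

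The gene changes after doxycycline were for the most part common to both genotypes, though the negative lines cannot switch on CA19-9 synthesis. The induced alleles are argued against as the whole cause, since 98.9% of the mouse genes called at 24 h in inducible lines had the same sign in negative lines. With libraries thinned to equal depth at least 89.5% of the called genes kept their call and sign in both genotypes, with and without the replicate block. With a trend on GC content and length corrected at least 91.7% did. This argues against depth and such a trend as the whole cause. The planned offset for effective length, without the block, kept only 455 of 812 calls in inducible lines and 351 of 625 in negative lines. That offset corrects shifts in a gene's mean effective length between libraries, not a trend on length across genes. A part of such shifts therefore stays open. As a hypothesis, doxycycline itself may drive the response. Doxycycline alone and rtTA3 bound by doxycycline cannot be told apart, because 0 of the 15 libraries had rtTA3 under 1 CPM.

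Some genes raised at 4 h in inducible lines lie next to one another: Tmem165, Clock and Nmu on chromosome 5, with gaps of 622 and 28702 bp, and Csf1 and Gstm5 on chromosome 3, 135351 bp apart. Shared reads are argued against, with 0% of the 31-mers of these neighbours' transcripts in common, and so is a rise of all genes within 1 Mb, since the 45 genes there, raised ones included, had a median log2 change of 0.04 (quartiles -0.02 and 0.17) against 1.26 for the raised ones. A rise over a shorter stretch was not tested. Chance placement remains open: 5 of 35 raised mouse genes had a raised neighbour within 1 Mb, and a share of 0.0696 of 10000 random sets, with 1.92 such genes on average, had as many. In negative lines Clock rose (1.25, edgeR adjusted p = 0.00815), while Tmem165 (1.24), Csf1 (1.17) and Gstm5 (0.86) did not pass (edgeR adjusted p = 0.0518 for each; 0.000111, 0.000367 and 0.000115 with the replicate block), and no biological explanation was tested.

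In the fit with the replicate block 3 processed pseudogenes responded differently in the genotypes, at mean levels of 0.614, 0.658 and 0.764 CPM. They are Gm10221 (18.51 log2 units at 4 h, edgeR adjusted p = 0.00768), Gm9845 (8.94 at 24 h, edgeR adjusted p = 0.0115) and Gm5537 (-19.39 at 24 h, edgeR adjusted p = 0.00428), fitted values that rest on groups at or near 0 counts and are no bounds. Reads assigned differently between these copies and their closest genes may account for this: 100% of the 31-mers of each occur in transcripts of other genes, those of Gm10221 in Atp5l, Gm9845 in Cflar and Gm5537 in Pgk1. That value shows that reads can be shared, not that sharing made the difference. A response to the induced alleles, the biological alternative, stays open.

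Lists of genes whose responses differed between genotypes are given as values. Hypoxia and glycolysis genes differed at 4 h (camera adjusted p = 7.67e-07; 4.45e-09 with the replicate block; adjusted p = 1 with an estimated correlation), with opposite directions in the 2 genotypes and no call without negative 4 h A223 (0.0863). Of lists that did not pass with all libraries and no block, the unfolded protein list differed at 4 h in the fit with the replicate block (camera adjusted p = 0.0372). Inflammation (0.00151), proliferation (0.0357) and hypoxia and glycolysis genes (0.0364) did so at 24 h. Without the block, camera with an estimated correlation gave adjusted p = 1 for the unfolded protein list and 0.974 for each of the others. Without the block each of these also passed when certain single libraries were left out. The lowest camera adjusted p at 24 h was 0.0354 for inflammation and 6.16e-06 for proliferation without inducible 24 h A220. It was 0.000267 for hypoxia and glycolysis without inducible 0 h A217. These are the most favourable fits, and without inducible 24 h A217 no list passed at 24 h.

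The 6 inducible libraries at 0 and 4 h, and those at 0 and 24 h, can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave the most genes at both times, 1 of 10 splits, with 49 genes at 4 h against 0 in the highest of the others, and 812 at 24 h against 0. Of the 10 splits 4 part all 3 lines, and both the others of these and the splits that part fewer lines gave at most 0. Single outlying libraries were not tested for, and each library was left out in turn instead, which gave 2002 genes at 24 h without 24 h A217.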

How the results depend on the processing

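Thinning, the correction of GC content and length, and the leaving out of libraries in the list tests were chosen only after the results were seen; the cause of the changes below was not tested except where said. Counts are of features called by edgeR in inducible lines at 4 h (49) and 24 h (812), in negative lines at 4 h (20) and 24 h (625), for the difference of responses (2 and 2) and for genotype at 0, 4 and 24 h (0, 2 and 2). The count of 0 has 589 features with an unadjusted p under 0.05.

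The fit with the organoid line as a replicate block takes differences between lines out of the spread (biological coefficient of variation 0.058 against 0.157). Its counts were 502, 3987, 336 and 3696 for the time comparisons, and 4 for the difference at 24 h. With the line as a random replicate block in limma-voom they were 273, 3399, 163 and 3135. DESeq2 called 143, 1804, 96 and 1483, 5 for each difference of responses, and 5, 11 and 14 between genotypes. With an offset for effective length 512 and 392 genes were called at 24 h. In the compared groups alone, 20 and 65 were called in inducible lines and 1734 at 24 h in negative lines. Libraries of a group differed more in inducible lines (chi-square per degree of freedom 24.6 to 47.45) than in negative lines (16.02 to 20.52). The spread shared by all 15 libraries may thus be too small for inducible lines and too large for negative lines. At 24 h, thinned libraries with the replicate block gave 3892 and 3584, the GC and length correction gave 1229 in inducible lines, and with the replicate block it gave 4573 and 4173. Median-of-ratios scaling, no filter, a stricter filter, leaving out the most abundant gene, thinning without the block (748 and 609) and the correction without the block in negative lines (872) stayed within 1.5 times.

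Leaving out 1 library or line gave 10 to 35 and 57 to 2002 genes in inducible lines at 4 and 24 h, and 0 to 9 and 9 to 129 in negative lines. It gave 1 to 2 for each difference of responses, and 0 to 3, 2 to 6 and 2 to 6 between genotypes. A group left with 1 library is assumed to vary like the other groups. These fits held no replicate block, so a call lost there, above all in negative lines, can reflect few unpaired libraries. Of 161 named calls 25 held in every fit without 1 library or line. The replicate block kept all 157 it could test. It called 184 of 208 named results not called in the main test, but the naming rule took genes from that fit. That count therefore carries no weight as a check. Of the 161 calls 161 held with limma-voom, 155 with DESeq2, 160 with median-of-ratios scaling, 120 with the length offset and 89 in the compared groups alone.

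Lists past camera's threshold numbered 6, 10, 10 and 7 for the time comparisons, 1 and 0 for the differences and 1, 3 and 2 between genotypes. With an estimated correlation they numbered 2, 0, 1 and 0, then 0 and 0 for the differences and 0, 0 and 0 between genotypes; fry gave 2, 4, 1 and 3, then 0 and 0 for the differences and 0, 1 and 0 between genotypes. In camera with the replicate block 2 and 3 lists differed in their responses. Without 1 library the lists numbered 3 to 9, 8 to 10, 5 to 7 and 3 to 9 for the time comparisons, 0 to 5 and 0 to 3 for the differences, and 0 to 2, 2 to 8 and 1 to 3 between genotypes. The hypoxia and glycolysis list at 4 h in inducible lines had camera adjusted p from 1.06e-06 without 4 h A225 to 0.935 without 0 h A220, where it turned to higher (0.00579 with the replicate block, 0.769 with an estimated correlation). No list past the threshold had a median that changed sign under another scaling, and the median over all genes shifted by -0.03 at most. Beyond the calls named beside the results, the block changed no list call.

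The 95% intervals of the differences of responses reached 0.32 log2 units to either side in the median gene, and 0.23 in the fit with the replicate block.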

Other observations

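No test was chosen for this part after the results were seen, while the added sequence Puro was picked after its values were seen.

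Single members of lists that did not pass at 24 h changed by then in inducible lines. The metallothioneins Mt1 and Mt2, which bind zinc and copper, rose (log2 change 0.7 and 1.04, edgeR adjusted p = 0.0216 and 0.0221), as did Slc30a1, a zinc exporter (0.51, edgeR adjusted p = 0.00136), and G6pdx, the enzyme that supplies NADPH (0.2, edgeR adjusted p = 0.0382), while Mt2 stood at 18.3 ± 4.59 CPM at 4 h, 29.9 ± 6.01 at 0 h and 61.4 ± 13.6 at 24 h (SD, n = 3). The NRF2 and metal list as a whole did not pass at 24 h (camera adjusted p = 0.065), except without 24 h A220 (0.0314), with 4 of 21 genes higher and 5 when adjusted over the list alone. The small heat shock protein Hspb1 rose from 5.74 ± 1.96 to 17.3 ± 5.1 CPM (edgeR adjusted p = 0.0105), the only 1 of 14 heat shock genes called, with 2 when adjusted over the list alone. Among 34 interferon genes the RNA sensor Ddx58 and the interferon-induced gene Ifi27 were some of those that rose (0.5 and 0.55), with 5 higher when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.065). Of 20 p53 targets the cell cycle inhibitor Cdkn1a (0.65) and the desmosome protein Perp (0.75) rose and Gtse1 (-0.33) fell, 3 and 2 when adjusted over the list alone (camera adjusted p = 0.425). Of 15 circadian genes Clock rose and its repressor Ciart fell (-0.81, edgeR adjusted p = 0.0218), 1 and 2 when adjusted over the list alone (camera adjusted p = 0.996). Slc30a1, Ddx58 and Clock kept the call without each single library. The other genes lost it without at least 1. The highest value was reached by G6pdx (edgeR adjusted p = 0.165), Perp (0.0963), Ifi27 (0.0734) and Hspb1 (0.0504) without 0 h A217, Mt1 (0.0985) and Mt2 (0.0997) without 24 h A220, and Cdkn1a (0.144), Gtse1 (0.101) and Ciart (0.0831) without 24 h A225.

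In negative lines at 24 h, Mt2 (1.1, edgeR adjusted p = 0.0449), Slc30a1 (0.46, 0.0104), Hspb1 (1.79, 0.0184), Ifi27 (0.69, 0.0147) and Perp (0.78, 0.0462) rose too, with the apoptosis gene Pmaip1 (0.65, 0.0103). The fit with the replicate block kept these calls. Each lost the call without any 1 of the 4 libraries, in fits with no replicate block that leave 1 library in a group. The highest edgeR adjusted p was 0.272 for Mt2 and 0.146 for Ifi27 without 24 h A223, 0.121 for Slc30a1 without 0 h A223, 0.165 for Hspb1 and 0.104 for Pmaip1 without 0 h A218, and 0.273 for Perp without 24 h A218.

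The Puro sequence, a puromycin resistance gene among the added sequences, differed more by line than by time. As a share of each library's total, without TMM scaling, it stood at 4.09 to 5.08 CPM in the 3 libraries of A217 and at 0.58 to 1.63 in those of A220, was at 0.06, 0.12 and 0.09 in those of A218, and had 0 counts in A223 and A225.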
